A study of Mus musculus with 12 samples.

How the data were processed

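Gene expression was measured by RNA sequencing in primary mouse embryonic fibroblasts carrying floxed Htt alleles. Per the labels, cells from day 13.5 embryos were transduced with a lentivirus encoding Cre recombinase and GFP (HTT-deleted) or with a control lentivirus encoding an H2B-eGFP fusion, and were harvested 7 days later. Ribosomes were then purified, and 1 part in 15 of the same cell suspension was kept for total RNA. The RNA quality number was above 9 in all samples, and stranded libraries were made from 250 ng of RNA. The 12 samples make 4 groups of 3. The labels count replicates as independent when they came from different primary cultures or from separate passages. The p-values of single genes therefore measure the spread between such cultures or passages. Those of camera list tests and Fisher's exact test take genes as units, and that of the chi-square test takes reads.

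Per the submitters' processing notes, the authors used FastQC, aligned reads with STAR 2.7.2b and counted them with HTSeq 0.11.1 on GRCm38 (mm10). The authors deposited raw read counts per Ensembl gene for each library. The annotation release and the strand setting of the counting are not given in the sources used here. Each library lists 55487 genes, of which 55394 had a symbol in the reference table used here, and 5 summary entries that name no gene. Those entries were kept out of library sizes and tests. How reads matching several places affected mitochondrially encoded genes was not tested, and the low counts of mt-Co3 and mt-Atp6 may come from the counting or the annotation. Among reads assigned to a gene, to several genes or to none, the share in no feature was 6.94 to 7.73% in total RNA and 2.64 to 3.30% in ribosome-associated RNA. A separate deposited table gives the authors' own comparison per fraction, with log2 fold changes, mean log2 CPM, a likelihood ratio score, a p-value and a false discovery rate. Its name speaks of RUVSeq, a method that adds factors of unwanted variation to the model, with 2 factors. Which RUVSeq method, filter and scaling the authors chose is not given in the sources used here.

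Gene counts per library summed to 16789356 to 30571501. Counting error is small at that depth for all but rare transcripts, and intervals and floors given for rare ones cover counting error only. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom between replicates was 35.1 to 178, so all 12 were kept as separate samples.

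Counts were scaled by TMM and filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3. Each comparison used edgeR's quasi-likelihood test with robust fitting, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were HTT-deleted against control in total RNA (14759 genes), the same in ribosome-associated RNA (14588 genes), the difference of these effects as an interaction term over all 12 libraries (15574 genes), and ribosome-associated against total RNA in control cells (14990 genes). The interaction is the change in the ratio of ribosome-associated to total RNA per gene. Standard errors are the log2 fold change divided by the square root of F. CPM are on the TMM scale, and log2 CPM used a prior count of 2. Tests, alternatives, the rule for named genes and 40 gene lists of pathways, complexes and cell types were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation and fry stood beside it.

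The replicate numbers were treated as pairing the samples. Same-numbered control and HTT-deleted libraries deviated together from their group means, with correlations across genes of 0.222, 0.575 and 0.445 in total RNA and 0.577, 0.743 and 0.681 in ribosome-associated RNA. Same-numbered total and ribosome-associated libraries come from the same suspension per the labels, with correlations of 0.501, 0.737 and 0.651 in controls. Values from fits with the replicate number as a block are therefore given where they change a call or a count. The interaction was blocked by the 6 cultures.

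Named genes were Htt and, of called genes with at least 1 CPM in a group, a symbol other than a provisional name, no pseudogene biotype and groups that do not overlap, the 8 with the largest rise and the 8 with the largest fall. Where none was called, the 5 with the smallest p were named. Lists past the threshold gave their members with the smallest p in the list's direction. Where the fit without a block called nothing, the rule was also applied to the blocked fits, with the same direction in every pair in place of groups that do not overlap, a use chosen after seeing the data.

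Alternatives were other scalings (RLE, upper quartile), no filter, a filter at 5 CPM in 3 libraries, DESeq2 1.42.0, limma voom, the block, 2 factors of unwanted variation estimated from residuals, all 12 libraries in 1 fit, and each library left out in turn. Blocked fits on pairs 2 and 3 alone, blocked fits without another pair, and the block joined to another tool, scaling or filter were added after seeing the data, as was the histone list less Hist1h2bf and Hist1h2bm. Transcript lengths and coordinates came from GENCODE M21, which is on GRCm38. No other columns of per-sample values were left out.

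The scripts were tested on simulated counts drawn with the means, library sizes and dispersions of these libraries, with 200 genes changed, after the deposited counts had been fitted. In total RNA (14464 genes) the test recovered 80.3% of 4-fold changes and 8.96% of 2-fold changes. In ribosome-associated RNA it recovered 86.4% and 76.1% (14361 genes), and with the block 98.5% and 89.6% (14374 genes). For the interaction (15366 genes) it recovered 57.6% and 5.97%, and for the baseline comparison (14747 genes) 93.9% and 46.3%. Of 1.5-fold changes it recovered 0 of 67 in total RNA, 8.96% in ribosome-associated RNA, 1.49% in the interaction and 20.9% in the baseline comparison. With the block these were 0 of 67, 77.6% and 2.99% in the first 3. Genes left unchanged made up 7 of 66 calls in total RNA, 9 of 124 in ribosome-associated RNA, 3 of 46 in the interaction and 13 of 120 in the baseline comparison. With the block they made up 6 of 90, 27 of 224 and 13 of 102 in the first 3, and all these shares are above the nominal 5%. A simulated list of 40 genes raised 1.3-fold passed in all 4 comparisons, and 0 of 20 unchanged lists did. Genes were drawn independently of each other, so this does not test how often lists pass when their genes vary together. Nor do the recovery shares of single genes carry over directly to the deposited counts. There Htt, 4.47-fold lower in total RNA, was not called (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.812). Other splits of the real libraries passed up to 16 lists in total RNA and 18 in ribosome-associated RNA.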

Results

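The libraries profiled fibroblasts from mouse embryos in which Htt, the gene for the scaffold protein huntingtin, was left intact or deleted by Cre recombinase. Total RNA and ribosome-associated RNA, the transcripts recovered with a ribosome pellet, were sequenced from the same cultures, with 3 control and 3 HTT-deleted libraries of each kind. The series asks how loss of huntingtin alters the transcriptome and the RNA held on ribosomes. Gene counts ran from 16789356 (ribosome-associated control, replicate 1) to 30571501 (ribosome-associated control, replicate 3). Total RNA libraries detected 20316 to 22035 genes and ribosome-associated libraries 19446 to 20496. The first principal component, with 35.8% of the variance, separated the fractions apart from total HTT-deleted replicate 1, whose score of 16.75 lay within the 12.49 to 51.09 of the ribosome-associated libraries, while the 5 other total libraries were at -55.45 to -35.90.

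A total library stood apart. In total RNA of HTT-deleted replicate 1, short transcripts were over-represented: across 9929 protein-coding genes, its deviation from the other total libraries had a Spearman correlation of -0.607 with transcript length, against 0.240 to 0.457 in the 5 other total libraries. These genes are not independent replicates. Each of the 5 others was set against a mean that holds this library, which pushes their correlations up. In total HTT-deleted replicate 1 the shortest 10% of transcripts lay 0.87 above the other libraries on the log2 scale and the longest 10% at -0.65. Transcripts encoded by mitochondrial DNA made up 0.854% of its gene counts, against 1.37 to 1.98% in the 5 others. Ribosome-associated control replicate 1 leaned the same way, with a length correlation of -0.543 against 0.0161 to 0.191 in the 5 other ribosome-associated libraries, its shortest transcripts at 0.18 and its longest at -0.25. The SD of its deviation was 0.249, against 0.249 to 0.343 in those libraries, while that of total HTT-deleted replicate 1 was 0.724.

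Htt itself (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534, plus strand, GRCm38) was lower in every HTT-deleted library than in any control library of its fraction. In total RNA it averaged 56.4 ± 9.64 CPM in controls and 12.3 ± 2.81 CPM in HTT-deleted cells (SD, n = 3 each), a log2 fold change of -2.16 (SE 0.24). In ribosome-associated RNA the means were 24.9 ± 6.26 and 7.28 ± 4.82 CPM (SD, n = 3 each), a log2 fold change of -1.78 (SE 0.47). HTT-deleted replicate 1 kept the most in the ribosome fraction, at 12.8 CPM against 5.04 and 3.98 in the others. The unadjusted p from edgeR's quasi-likelihood test was 5.5e-05 in total RNA and 0.00833 in ribosome-associated RNA, and the Benjamini-Hochberg adjusted p over all genes was 0.812 and 1. DESeq2 with Benjamini-Hochberg adjustment called Htt in total RNA (adjusted p = 7.0e-12). The labels do not say which exons are flanked, and the counts cover the whole gene.

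**Figure D1:**
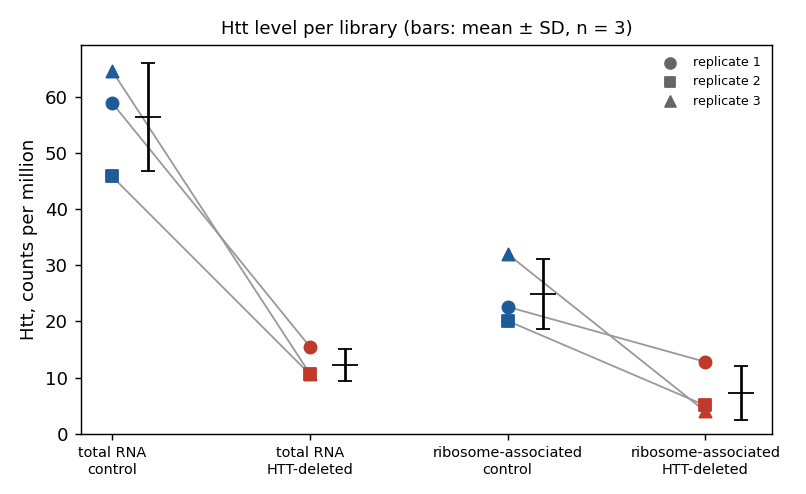
Htt level per library in CPM (vertical axis, from 0) for the 4 groups; symbols mark replicates, grey lines join control and HTT-deleted libraries of the same number, and bars give mean and SD (n = 3). HTT-deleted libraries lie at 10.6 to 15.5 in total RNA, below all control libraries at 45.8 to 64.6.

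In total RNA, macrophage markers stood highest in HTT-deleted cultures relative to controls. All 18 tested markers had log2 fold changes above 0, with a median of 0.88, among them C1qa, a chain of complement C1q (1.48, SE 0.81), and Fcer1g, the shared signalling chain of Fc receptors (1.35, SE 0.71). The list passed camera (adjusted p = 2.8e-10, and adjusted p = 0.777 with an estimated correlation). With the replicate number as a block, 17 of the 18 markers rose when adjusted over the list alone, and 0 did so without the block. The mean of the markers was 5.48 ± 0.99 log2 CPM in controls and 6.34 ± 0.92 in HTT-deleted cells (SD, n = 3 each), and it was higher in the HTT-deleted library of all 3 pairs. The median ran from 0.16 (without HTT-deleted replicate 1) to 1.56 (without control replicate 1) with each library left out, was 0.55 without control replicate 2, and the list passed each time.

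**Figure D2:**
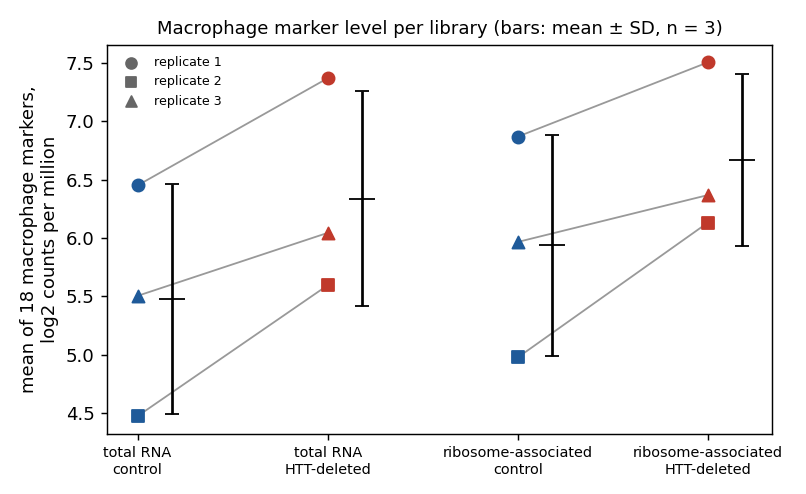
Mean log2 CPM of 18 macrophage markers (vertical axis) per library in the 4 groups; grey lines join libraries of the same replicate number and bars give mean and SD (n = 3). Each line rises from control to HTT-deleted, while controls alone span 4.47 to 6.45 in total RNA.

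Machinery genes with short transcripts also rose as lists in total RNA, but this rested on the library that stood apart. Cytosolic ribosomal proteins had a median log2 fold change of 0.49 with 81 of 82 above 0 (camera adjusted p = 5.0e-14, and adjusted p = 0.777 with an estimated correlation), nuclear-encoded respiratory chain subunits 0.47, mitochondrial ribosomal proteins 0.32 and proteasome subunits 0.31. The adjusted p with an estimated correlation was 0.777 for each list past camera in total RNA. Examples were Rpl27 (0.52, SE 0.30), Ndufa5 (0.96, SE 0.51), Mrpl11 (0.64, SE 0.39) and Psmb6 (0.60, SE 0.40), none of which passed alone. In pairs 2 and 3 with the block, an alternative chosen after seeing the data, the 4 medians were -0.11, -0.0944, -0.0419 and -0.0508, and without HTT-deleted replicate 1 alone they were -0.0932, -0.0784, -0.0146 and -0.0489. Ribosomal proteins (camera adjusted p = 6.3e-09), respiratory chain subunits (1.2e-08) and proteasome subunits (0.00335) passed camera in the lower direction in pairs 2 and 3, with an adjusted p = 0.811 at an estimated correlation. ATF4 and integrated stress response targets (0.17; Mthfd2, a mitochondrial folate enzyme, at 0.44, SE 0.21) and translation factors (0.11; Mcts1 at 0.40, SE 0.26) rose as lists too, and translation factors lost the call with the block (camera adjusted p = 0.127) and were at -0.0229 in pairs 2 and 3. Lists that fell, in the same libraries in which macrophage markers rose (median 0.88), were YAP and TEAD targets (median -0.21; Crim1 at -0.37, SE 0.19), collagens and fibrillar matrix (-0.16; Fbln2 at -0.36, SE 0.23), inflammatory and NF-kB genes (-0.11; Mmp13, a collagenase, at -0.81, SE 0.37) and replication-dependent histones (-0.24). The histone call rested on Hist1h2bf and Hist1h2bm: without them, a test added after seeing the data, the 14 others had a median of -0.11 and did not pass (camera adjusted p = 0.317). Several of these calls ended with 1 library left out: ATF4 targets without HTT-deleted replicate 1 (0.0354), HTT-deleted replicate 2 (0.16) or control replicate 3 (0.14), translation factors without control replicate 1 (0.0998) or 2 (0.0947), collagens without HTT-deleted replicate 1 (0.00290) or control replicate 2 (-0.0382), inflammatory genes without control replicate 1 (-0.13) or HTT-deleted replicate 2 (-0.0814), and histones without control replicate 2 (0.0455). Of 38 lists, 11 passed camera, and 0 did so with an estimated correlation or with fry.

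No single gene was called in total RNA by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 of 14759, with 44 at an unadjusted p under 0.05. DESeq2 called 3, all lower, and limma voom 0. With the block the count stayed at 0, with 350 at an unadjusted p under 0.05. Both 44 and 350 are a smaller share of 14759 than the 0.05 expected if no gene changed. These p-values thus ran large, and 0 calls does not show that no gene changed. The 5 genes with the smallest p, all failing the threshold, were Htt, Hist1h2bf, Hist1h2bm, AC166110.4 (1.60, SE 0.43) and Msantd1 (-2.23, SE 0.60), a gene on chromosome 5 (34908012 to 34923839) whose annotation overlaps the end of Htt by 4523 bp.

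Without pair 1, and with the block, 94 genes were called in total RNA, of which 78 rose and 16 fell (edgeR's quasi-likelihood test, Benjamini-Hochberg). This fit holds only pairs 2 and 3, so its standard errors lean on variance shared across genes, and the simulation did not cover it. With all 3 pairs and the block the same test called 0 genes (lowest adjusted p = 0.902). The largest rises were Cd5l, a scavenger protein secreted by macrophages (2.24, SE 0.39), Cd37, a leukocyte tetraspanin (1.37, SE 0.26), Bin2 (1.32, SE 0.20), Adap2 (1.29, SE 0.26), the transcription factor Pou2f2 (1.21, SE 0.19), Arl11 (1.21, SE 0.20) and Tlr8 (1.16, SE 0.20), and Gatm, an enzyme of creatine synthesis (1.28, SE 0.20). The largest falls were those of Hist1h2bf and Hist1h2bm, each with 0 to 2 counts per HTT-deleted total library. Other falls included Htt (-2.35, SE 0.12), Msantd1 (-3.28, SE 0.53), the oxidised LDL receptor Olr1 (-2.20, SE 0.36), and the mesothelial and epithelial surface genes Msln (-1.75, SE 0.31) and Upk1b (-1.45, SE 0.26), as well as Ugcg, which makes glucosylceramide (-0.50, SE 0.07). Msantd1 averaged 0.329 ± 0.29 CPM in the 3 HTT-deleted total libraries (SD), where a floor of 3 counts per library is 0.163 CPM. Its fold change thus rests on few reads. Several of the genes named here had the opposite sign in pair 1: Bin2 (-1.10), Adap2 (-0.56), Gatm (-0.73), Tlr8 (-3.75), Msln (0.38) and Upk1b (0.60). Over all 3 pairs without the block these 6 were at 0.21, 0.42, 0.19, -0.31, -0.82 and -0.79, none past the threshold.

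Macrophage markers also stood highest in ribosome-associated RNA. All 18 lay above 0, with a median log2 fold change of 0.74 (camera adjusted p = 2.8e-10, and adjusted p = 0.887 with an estimated correlation). With the replicate number as a block the median was 0.79, with 10 of the 18 called over all genes and 17 when adjusted over the list alone. Lyz2, lysozyme and the most abundant marker, was at 1670 CPM in controls and rose by 0.90 (SE 0.12) on the log2 scale in that fit (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00175). Ctss, a lysosomal protease, rose by 0.82 (SE 0.11) and Mrc1, a mannose receptor, was at 0.91 (SE 0.24) without passing. The mean of the markers was 5.94 ± 0.95 log2 CPM in controls and 6.67 ± 0.74 in HTT-deleted cells (SD, n = 3 each). Without the block the list's median ran from 0.15 (without HTT-deleted replicate 1) to 1.31 (without control replicate 1), and was 0.36 without control replicate 2.

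Without the block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14588 genes in ribosome-associated RNA, with 110 at an unadjusted p under 0.05, DESeq2 1 and limma voom 0. These 110 are a smaller share of 14588 than the 0.05 expected if no gene changed, so the p-values without the block ran large. With the block 247 genes were called, of which 213 rose and 34 fell. The 213 rises had a median log2 fold change of 0.68, a 1.6-fold change, with pair medians of 0.67, 0.96 and 0.40. Largest were Cd5l (1.92, SE 0.27), Slc24a5, an ion exchanger of melanosomes (1.26, SE 0.26), the calcium-permeable channel Trpm2 (1.18, SE 0.30), Naip5, a sensor of bacterial flagellin (1.17, SE 0.27), the leukocyte receptor Ly9 (1.16, SE 0.17), Vwf, the von Willebrand factor of endothelium and platelets (1.15, SE 0.18), and the Toll-like receptors Tlr1 (1.13, SE 0.19) and Tlr8 (1.13, SE 0.16). In pairs 2 and 3 alone 14 were called, 11 higher, led by Hk3, Cd180, Tlr13, Lilrb4a and Ptprc (0.74 to 0.86). That fit too leans on variance shared across genes.

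Falls in the same fit were led by a pair of histone H2B genes. Hist1h2bm had 20 to 335 counts per control library and 0 to 1 per HTT-deleted library in ribosome-associated RNA, a ratio of 523 (95% counting interval 93.4 to 20700). Hist1h2bf had 65 to 685 and 0 to 7 counts, a ratio of 156 (75.2 to 388). In total RNA the ratios were 123 (33.9 to 1020) for Hist1h2bm and 171 (58.4 to 833) for Hist1h2bf. Per the labels only the control vector encodes an H2B fusion, so a fall of these genes cannot be told apart from reads of the vector. Smaller falls were those of Kng1, a kininogen (-1.50, SE 0.29), Prl3a1 (-1.22, SE 0.24), Upk1b (-1.18, SE 0.20), the macrophage elastase Mmp12 (-1.10, SE 0.18), Olr1 (-1.10, SE 0.24) and the secreted Wnt antagonist Frzb (-0.63, SE 0.14). Without the block, the smallest p outside the histones belonged to Cebpb (-0.40, SE 0.10), Slc24a5 (1.31, SE 0.34) and Ip6k3 (1.26, SE 0.33), none past the threshold.

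Several lists were slightly lower on ribosomes, in the same libraries in which macrophage markers rose (blocked median 0.79). Inflammatory and NF-kB genes had a median log2 fold change of -0.23 (camera adjusted p = 1.1e-05, and adjusted p = 0.603 with an estimated correlation; Mmp3, stromelysin, at -0.65, SE 0.23). The adjusted p with an estimated correlation was 0.603 for senescence-associated genes and 0.887 for the other lists that fell. Lower too were YAP and TEAD targets, at -0.11 with 19 of 21 below 0 (Ccn1 at -0.36, SE 0.13; Ccn2 at -0.34, SE 0.11), and myofibroblast and actin genes -0.14 with 21 of 22 below 0 (Tpm2 at -0.35, SE 0.15). With the block, 6, 4 and 2 members of the inflammatory, YAP and TEAD, and myofibroblast lists fell when adjusted over the list alone. Senescence-associated genes (-0.0869; Igfbp3 at -0.32, SE 0.16), collagens and fibrillar matrix (-0.0966; Fbln1 at -0.34, SE 0.14), p53 targets (-0.10; Gadd45a at -0.26, SE 0.14) and snoRNA host genes (-0.16; Snhg18 at -0.25, SE 0.12) also fell as lists. So did cytosolic ribosomal proteins (-0.0904; Rpl26 at -0.40, SE 0.15), respiratory chain subunits (-0.0482; Atp5o at -0.50, SE 0.18), mitochondrially encoded genes (-0.11; camera adjusted p = 0.0840 with the block, which ended the call), endoplasmic reticulum chaperones (-0.0760; Calr at -0.20, SE 0.12), cytosolic chaperones (-0.0348; Bag3 at -0.17, SE 0.09) and replication-dependent histones (-0.0428, 8 of 16 below 0). In the mitochondrially encoded list the member with the smallest p was mt-Co3 (-0.78, SE 0.47), a gene at 11.7 CPM in controls against 8690 for mt-Co1, with differences of -1.69, -0.0616 and 0.0411 in pairs 1, 2 and 3. Whether its low counts reflect the counting of reads rather than its level was not tested. The histone call again rested on Hist1h2bf and Hist1h2bm, and the 14 others had a median of 0.0295 and did not pass (camera adjusted p = 0.639). Of 38 lists 14 passed camera, 1 up and 13 down, and 0 passed with an estimated correlation or fry. Leaving out ribosome-associated control replicate 1 left 8 lists.

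Of the 14 lists on ribosomes, macrophage markers (0.15 to 1.31), inflammatory genes (-0.30 to -0.14) and senescence-associated genes (-0.32 to -0.0674) kept the call with each library left out. Ribosomal proteins lost it without control replicate 1, the library leaning to short transcripts (0.00444), or HTT-deleted replicate 3 (-0.0235), respiratory chain subunits without these 2 libraries (0.0274 and -0.00434), and YAP and TEAD targets without control replicate 2 (-0.0331). Myofibroblast genes lost it without control replicate 2 (-0.0610) or HTT-deleted replicate 3 (-0.0596), histones without control replicate 2 (0.0230), and collagens without HTT-deleted replicate 1 (-0.0303), control replicate 2 (0.0678) or HTT-deleted replicate 3 (-0.0647). For mitochondrially encoded genes (-0.0366, -0.0597 and -0.0789) and snoRNA host genes (-0.0612, -0.0880 and -0.0659) the call ended without control replicate 1, control replicate 2 or HTT-deleted replicate 3. Endoplasmic reticulum chaperones lost it without control replicate 1 (-0.0872), HTT-deleted replicate 1 (-0.0540) or control replicate 2 (-0.0240), cytosolic chaperones without control replicate 1 (-0.0356), HTT-deleted replicate 2 (-0.0140) or control replicate 3 (-0.0367), and p53 targets without HTT-deleted replicate 1 (-0.0379), HTT-deleted replicate 2 (-0.0470) or control replicate 3 (-0.0602).

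**Figure D3:**
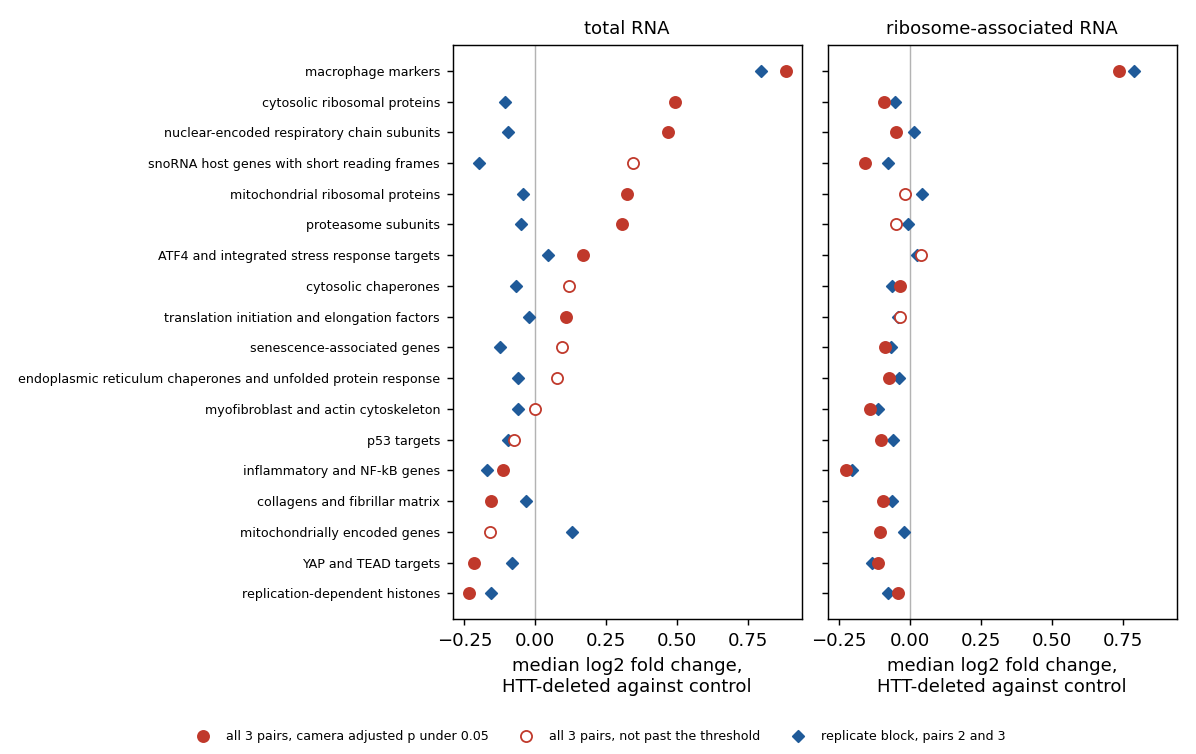
Median log2 fold change of HTT-deleted against control (horizontal axes) for lists past the camera threshold in total RNA (left) or ribosome-associated RNA (right); filled circles passed with all 3 pairs, open circles did not, and diamonds give the blocked fit on pairs 2 and 3. Macrophage markers lie at 0.74 to 0.88 in circles and 0.79 to 0.80 in diamonds, while ribosomal protein and respiratory chain lists are near 0.5 in total RNA only with pair 1 included.

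The change in ribosome-associated RNA relative to total RNA was lower for the same machinery lists. Cytosolic ribosomal proteins had a median interaction of -0.55 on the log2 scale with 81 of 82 below 0 (Rpl26 at -0.71, SE 0.26), respiratory chain subunits -0.48 (Atp5o at -0.77, SE 0.39), snoRNA host genes -0.50 (Snhg8 at -0.90, SE 0.49), proteasome subunits -0.30 (Psmd3 at -0.27, SE 0.16) and mitochondrial ribosomal proteins -0.30 (Mrps9 at -0.45, SE 0.26). Translation factors (-0.14), senescence-associated genes (-0.16) and cytosolic chaperones (-0.11) completed the 8 of 39 lists past camera. Their camera adjusted p ran from 1.5e-22 to 0.041, and the adjusted p was 0.886 for each with an estimated correlation. Without total HTT-deleted replicate 1, 0 lists passed, and in pairs 2 and 3 blocked by culture, 0 of the 8 passed in this direction. In that fit 5 of them passed camera in the opposite direction: respiratory chain subunits (0.11, camera adjusted p = 5.1e-12), mitochondrial ribosomal proteins (0.0829, adjusted p = 3.8e-04), cytosolic ribosomal proteins (0.0509, adjusted p = 0.00845), and proteasome subunits (0.0519) and snoRNA host genes (0.19), each at an adjusted p = 0.0146. With an estimated correlation their adjusted p was 0.895 to 0.950. With all 3 pairs, the culture block added myofibroblast and actin genes (-0.14, camera adjusted p = 0.0422, and 0.684 with an estimated correlation). Leaving out ribosome-associated control replicate 3 gave 13. Translation factors also lost the call without ribosome-associated HTT-deleted replicate 2 (-0.11) and snoRNA host genes without ribosome-associated HTT-deleted replicate 3 (-0.45). Senescence-associated genes lost it without total control 1 (-0.14), ribosome-associated HTT-deleted 1 (-0.0793), ribosome-associated control 2 (-0.0964) or total HTT-deleted 3 (-0.25), and cytosolic chaperones without total control 1 (-0.10) or 2 (-0.0842), ribosome-associated control 1 (-0.10) or 3 (-0.0743), ribosome-associated HTT-deleted 2 (-0.0830) or total HTT-deleted 3 (-0.17).

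No gene was called for a different response between the fractions by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment: 0 of 15574, with 85 at an unadjusted p under 0.05 (0 with DESeq2 or limma voom, and 0 with the culture block). These 85 are a smaller share of 15574 than the 0.05 expected if no gene differed, so 0 calls does not show that none did. Smallest p values belonged to Snhg10 (-1.30, SE 0.43), Zfp668 (-0.56, SE 0.19), Cd300ld4 (2.23, SE 0.81), Hist2h3c2 (-1.17, SE 0.42) and Cstad (-1.29, SE 0.47). Htt was at 0.42 (SE 0.53). Macrophage markers had a median interaction of -0.31 (camera adjusted p = 0.567). Across 14174 genes the effects in the fractions had a Pearson correlation of 0.342 (Spearman 0.161), and -0.137, 0.529 and 0.208 within pairs 1, 2 and 3. Genes are not independent replicates, and both fractions come from the same cultures: over the 9 other splits of the 6 cultures the covariance ran from -0.0108 to 0.127, against 0.0279 for the real split. Of the 213 blocked rises in ribosome-associated RNA, 210 were also above 0 in blocked total RNA, with a median of 0.64, and 152 were above 0 in all 3 total pairs (pair medians 0.30, 0.96 and 0.48). In the 3 other splits that part every pair, 51 to 142 of the 213 leading genes of a direction had the same sign in total RNA. Between the 78 rises of total RNA in pairs 2 and 3 and these 213, 56 genes were shared, against 1.17 for independent lists, which these are not, as they come from the same cultures.

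In control cells, the list with the highest median on ribosomes was that of cytosolic ribosomal proteins. They had a median log2 difference of 0.78 from total RNA, with 77 of 82 higher and 2 lower when adjusted over the list alone (camera adjusted p = 2.8e-46, and adjusted p = 0.573 with an estimated correlation). Rpl26 (1.18, SE 0.13), Rps28 (1.08, SE 0.15), Rpl38 (1.01, SE 0.12), Rpl31 (1.01, SE 0.14), Rpl39 (1.01, SE 0.12) and Rps29 (0.99, SE 0.13) were among the 8 largest rises, with the platelet chemokine Ppbp (1.01, SE 0.24) and the galectin Lgals1 (1.01, SE 0.13). Respiratory chain subunits (0.52; Ndufb11 at 0.66, SE 0.08), mitochondrial ribosomal proteins (0.38; Mrpl42 at 0.68, SE 0.08), proteasome subunits (0.38; Psmb7 at 0.65, SE 0.09), translation factors (0.29; Eif3i at 0.69, SE 0.11), senescence-associated genes (0.32; Cdkn2b at 0.48, SE 0.09), endoplasmic reticulum chaperones (0.27; Sec61b at 0.65, SE 0.10), cytosolic chaperones (0.23; Hspe1 at 0.74, SE 0.10) and lysosomal genes (0.22; Npc2 at 0.66, SE 0.11) were higher as lists, with an adjusted p of 0.573 to 0.920 at an estimated correlation. Macrophage markers had a median of 0.55, above that of respiratory chain subunits, and passed only with the block (0.54; camera adjusted p = 7.1e-07, and 0.560 with an estimated correlation), where 15 of 18 were called higher. NRF2 targets also passed only with it (0.16; adjusted p = 0.0492, and 0.598 with an estimated correlation), for 14 lists in place of 12. Single genes lost the call with 1 library left out and no block: Ppbp without total control 1 (0.89), total control 2 (0.97) or ribosome-associated control 3 (0.83), and Cdkn2b without total control 1 (0.45). Those fits ignored that the fractions share cultures. With the block and all libraries, edgeR's quasi-likelihood test called Ppbp (SE 0.16, adjusted p = 1.3e-04) and Cdkn2b (SE 0.08, adjusted p = 2.8e-04).

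Nuclear-retained and long noncoding RNAs were depleted from ribosomes, with a median of -1.63 and 21 of 22 below 0 (camera adjusted p = 2.2e-18, and adjusted p = 0.392 with an estimated correlation). Xist, the RNA that silences an X chromosome, averaged 199 ± 104 CPM in control total RNA and 2.12 ± 0.69 CPM in the ribosome fraction (SD, n = 3 each), a log2 difference of -6.58 (SE 0.52). Kcnq1ot1, an imprinted antisense RNA, was at -4.97 (SE 0.31) and Gm26917 at -3.61 (SE 0.17). The microRNA gene Mir99a had 16 to 35 counts per control total library and 0 in every control ribosome library, at least 7.38-fold lower at a floor of 3 counts per library. Other large falls were those of the microRNA gene Mir5125 (-4.83, SE 0.39) and Gpc2 (-4.36, SE 0.38). Near 0 on ribosomes were Phyhd1 (1 to 2 counts per control ribosome library; ratio of total to ribosome-associated RNA 31.0, 95% counting interval 13.0 to 96.6), H2-M5 (1 to 5 counts; 26.3, 12.5 to 66.2) and Tgfbr3l (1 to 3 counts; 22.7, 10.2 to 62.9). Huntingtin partners fell as a list (-0.36, estimated-correlation adjusted p = 0.573; the splicing factor Prpf40b at -1.19, SE 0.10, and Ago2 at -0.69, SE 0.09), as did sex-linked genes (-0.70, estimated-correlation adjusted p = 0.573; Uty at -0.87, SE 0.21). The sex-linked list includes Xist and was not tested without it. With no block, Uty lost the call without total control 1 (-0.68) or 3 (-0.85), or without ribosome-associated control 1 (-0.89), 2 (-0.78) or 3 (-0.93). Those fits ignored that the fractions share cultures. With the block and all libraries Uty was at -0.85 (SE 0.10, adjusted p = 1.9e-05 by edgeR's quasi-likelihood test), and the SE of Xist was 0.12. Htt was at -1.18 (SE 0.21; adjusted p = 0.0104, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

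In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 3745 of 14990 genes between the fractions, 1499 higher and 2246 lower on ribosomes, and 7524 with the replicate block (3647 and 3877). Of 924 tested long noncoding RNAs 20.5% were lower, against 14.2% of 13254 protein-coding genes (Fisher's exact test, two-sided, p = 4.8e-07). Genes are not independent replicates, so this p does not measure the spread between cultures. Of 38 lists 12 passed camera, 0 with an estimated correlation (adjusted p = 0.573 for cytosolic ribosomal proteins) and 11 with fry. Leaving out control total replicate 1, 2 or 3 left 1507, 2119 or 2197 genes, and the same comparison in HTT-deleted cells called 131, all lower, in a set that holds the total library standing apart.

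The authors' deposited table calls more genes. It rests on a likelihood ratio test over 16974 genes in total RNA and 16235 in ribosome-associated RNA, unlike the quasi-likelihood test and filter used here. The fits here with 2 factors of unwanted variation also called fewer genes than that table. At a false discovery rate under 0.05 the authors' deposited table holds 844 genes in total RNA (388 higher, 456 lower) and 683 in ribosome-associated RNA (506 higher, 177 lower). The 247 genes of the blocked ribosome fit were all among the latter. Fold changes in the authors' deposited table correlated with those of the fits without the block at 0.915 in total RNA and 0.991 in ribosome-associated RNA across genes, and at 0.999 in both with fits that added 2 factors of unwanted variation. In total RNA, 359 of the 844 genes in the authors' deposited table had the same sign in all 3 pairs here, and in ribosome-associated RNA 623 of 683. For the 456 genes listed as lower in total RNA by the authors' deposited table, the median log2 differences in pairs 1, 2 and 3 were -1.92, -0.13 and 0.00899.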

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

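The length test on the total RNA library that stands apart was set before its result was seen, while the tests on its reads outside genes, on the other HTT-deleted libraries and on other splits of the samples were chosen after the results were seen. A difference between the fractions in the effect of HTT deletion, tested as an interaction, singled out 8 gene lists. Their median differences, ribosome-associated minus total RNA on the log2 scale, were -0.55 for cytosolic ribosomal proteins, -0.48 for nuclear-encoded respiratory chain subunits, -0.30 for mitochondrial ribosomal proteins, -0.30 for proteasome subunits, -0.50 for snoRNA host genes, -0.14 for translation factors, -0.16 for senescence-associated genes and -0.11 for cytosolic chaperones. With an estimated correlation 0 lists passed, at an adjusted p = 0.886 for each of the 8. Without total HTT-deleted replicate 1, 0 lists passed. Of the 10 splits of the cultures, 5 gave at least the real 8 lists, with 10 the highest of the others. The list count thus did not set the real split apart, and 10 splits are too few for a share under 0.05 in any case. For single genes the real count was 0, the highest other 0, and all 10 splits gave as many by edgeR's quasi-likelihood test (85 at an unadjusted p under 0.05 in the real split; 0 called by DESeq2 or limma voom).

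Total HTT-deleted replicate 1 favoured short transcripts, and a loss of long transcripts is a candidate explanation. After a length trend was removed, the SD of its deviation over 9929 genes was 0.578, against 0.724 before and 0.360 in the next highest total library before removal, which argues against length as the whole cause. Its reads in no feature made up 7.73% of reads, the highest of the total libraries, which argues against ribosome-associated RNA mixed into it. The length correlations of HTT-deleted total replicates 2 and 3 were 0.451 and 0.398, within the 0.240 to 0.457 of the control total libraries. Replicate 1 is part of the mean that each was set against, which raises all of these values, so their sign tells nothing. That neither leaned further to short transcripts than the controls did argues against HTT deletion as the cause. What set this library apart besides length stays open.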

How the results depend on the processing

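The fits on pairs 2 and 3, on other pairs of cultures, and with the block joined to another tool, scaling, filter or correlation were chosen after the data were seen. Genes called in total RNA were 1 with no filter, 3 with DESeq2, 4 with 2 factors of unwanted variation, 14 with the block in DESeq2 and 94 with the block in pairs 2 and 3. In ribosome-associated RNA they were 1 with DESeq2, 247 with the block, 319 with 2 factors, 223 with the block and RLE, 164 with the block at 5 CPM, 199 with the block in DESeq2, 233 with the block in voom, 14 in pairs 2 and 3, 182 in pairs 1 and 3 and 581 in pairs 1 and 2. In the baseline comparison they were 7524 with the block and 131 in HTT-deleted cells. The block removes the spread between pairs, and for the other shifts the cause was not tested. Leaving out 1 library gave 0 to 0 genes in total RNA, in ribosome-associated RNA and for the interaction, and 1507 to 3251 in the baseline comparison. Scaling, filter or tool alone left the baseline count at 3463 to 4317.

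Htt in total RNA passed with no filter (-2.18), DESeq2 (-2.16), 2 factors (-2.18), the block in DESeq2 (-2.18) and pairs 2 and 3 (-2.35), with adjusted p from 6.2e-13 to 0.0416 there and up to 1.00 elsewhere. In ribosome-associated RNA it passed with the block in voom (-1.90) and in pairs 1 and 2 (-1.36). Leaving out 1 library gave -2.39 to -2.06 and -2.46 to -1.48. List counts were 0 with an estimated correlation in all 4 comparisons, with or without the block, and 0 with fry in 3 (11 in the baseline). In pairs 2 and 3 they were 13 in total RNA, of which 4 were among the 11 in the same direction, 8 in ribosome-associated RNA and 8 in the interaction, with estimated-correlation adjusted p of 0.811 or higher. New there, all lower, were snoRNA hosts (-0.20), p53 targets (-0.0966), cytosolic (-0.0695) and endoplasmic reticulum chaperones (-0.0616), nuclear-retained RNAs (-0.0776) and senescence (-0.13) in total RNA, neural markers (-0.17) in ribosome-associated RNA, and collagens (-0.0570), myofibroblast (-0.0587) and mitochondrially encoded genes (-0.13) in the interaction. With 1 library left out they ran 9 to 13, 8 to 17, 0 to 13 and 13 to 15. The histone list less Hist1h2bf and Hist1h2bm, chosen after the data were seen, did not pass in total (-0.11) or ribosome-associated RNA (0.0295), nor with the block (-0.12 and 0.0354), and its construction shows the cause. The overlap with the authors' deposited table was 247 in ribosome-associated RNA with the block.

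In pairs 2 and 3 these reversed, and the cause was not tested beyond the absence of pair 1: in total RNA cytosolic ribosomal proteins (-0.11), translation factors (-0.0229), mitochondrial ribosomal proteins (-0.0419), respiratory chain (-0.0944), proteasome (-0.0508), Tlr8 (1.16), Rpl37a (-0.13) and Psmb6 (-0.0377); in ribosome-associated RNA respiratory chain (0.0153) and mt-Atp6 (0.0909); in the interaction cytosolic ribosomal proteins (0.0509), mitochondrial ribosomal proteins (0.0829), respiratory chain (0.11), cytosolic chaperones (0.0223), proteasome (0.0519), senescence (0.0117), snoRNA hosts (0.19), Htt (-0.17), Psmb1 (0.0432), Cdkn2b (0.0878) and Snhg18 (0.00618). With 1 library left out, reversals lay in these ranges. Total RNA: cytosolic ribosomal proteins -0.0932 to 0.72, translation factors -0.0249 to 0.19, mitochondrial ribosomal proteins -0.0146 to 0.47, respiratory chain -0.0784 to 0.71, proteasome -0.0489 to 0.46, Bin2 -0.19 to 1.19, Adap2 -0.00194 to 1.24, Gatm -0.22 to 1.41, Tlr8 -0.88 to 0.65, Upk1b -1.24 to 0.53, Rpl37a -0.12 to 1.35, Psmb6 -0.0302 to 0.85 and Psmb3 -0.00971 to 0.75. Ribosome-associated RNA: respiratory chain -0.10 to 0.0274, collagens -0.23 to 0.0678, Upk1b -2.34 to 0.28 and mt-Atp6 -1.22 to 0.0559. Interaction: mitochondrial ribosomal proteins -0.46 to 0.0114, respiratory chain -0.72 to 0.0316, proteasome -0.45 to 0.0281, snoRNA hosts -0.75 to 0.0992 and Htt -0.26 to 0.71. Medians also crossed 0 while camera kept its direction for histones (-0.43 to 0.0455) and collagens (-0.32 to 0.00290) in total RNA, histones (-0.30 to 0.0230) and cytosolic ribosomal proteins (-0.15 to 0.00444) in ribosome-associated RNA, and cytosolic ribosomal proteins (-0.76 to 0.00130) in the interaction. Of the values of named genes, 664 of 700 in total RNA, 886 of 1098 in ribosome-associated RNA, 451 of 456 in the interaction and 478 of 526 in the baseline comparison kept direction and side of the threshold.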

Other observations

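The tests on the histone pair, on the vectors and on other splits were chosen after the results were seen, and the slope and length tests on macrophage genes before. No other cell-type list rose past the camera threshold. Adipocyte markers were nonetheless higher on average in the HTT-deleted library of all 3 pairs, by 0.0740 to 0.31 log2 CPM in total and 0.00900 to 0.16 in ribosome-associated RNA, against 0.54 to 1.12 and 0.40 to 1.16 for macrophage markers. In total RNA endothelial (0.0970 to 0.17) and skeletal muscle markers (0.17 to 0.21) were also higher in all 3 pairs, while endothelial markers were lower in all 3 ribosome-associated pairs (-0.0980 to -0.0440). Neural markers were lower in all 3 pairs of total (-0.19 to -0.0990) and ribosome-associated RNA (-0.32 to -0.16), and chondrocyte and osteoblast markers in all 3 total pairs (-0.38 to -0.16). Vwf was the only marker of these lists to rise in the blocked ribosome fit (1.15, SE 0.18). The most abundant tested marker of each list was as follows. In ribosome-associated RNA with the block, Spp1, an osteoblast and macrophage matrix protein at 3330 CPM in controls, was at 0.0413 (SE 0.0955), the adipocyte lipase Lpl (547 CPM) at 0.0476 (SE 0.0863), the neuronal Map2 (115 CPM) at -0.00970 (SE 0.0776), the endothelial receptor Flt1 (65.3 CPM) at -0.0936 (SE 0.11), Des of muscle (10.7 CPM) at -0.79 (SE 0.23) and the keratin Krt7 (2.13 CPM) at -0.67 (SE 0.31), none past the threshold. List medians without the block in total and ribosome-associated RNA were 0.22 and 0.0373 for adipocyte, 0.16 and -0.0764 for endothelial, 0.31 and -0.16 for skeletal muscle, 0.0410 and -0.33 for neural, -0.14 and -0.14 for chondrocyte and osteoblast and 0.0409 and 0.0465 for epithelial markers (4 tested, described only), and 0 erythroid markers were tested. With the block, neural (camera adjusted p = 0.0439) and chondrocyte markers (adjusted p = 0.0406) fell as lists in ribosome-associated RNA, with an estimated-correlation adjusted p = 0.790.

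Lists of pathways tied to huntingtin, and the other lists given here, did not pass camera in either fraction with all pairs included. That held with and without the replicate block. It does not show that these lists were unchanged, and an effect of HTT loss cannot be told apart from the difference between the vectors. Medians in total and ribosome-associated RNA were -0.0760 and 0.0268 for huntingtin partners, 0.0694 and 0.00250 for REST-repressed neuronal genes, 0.00346 and 0.0290 for microtubule motors and dynactin, -0.10 and 0.0161 for autophagy, -0.10 and -0.0120 for cilium genes and 0.0796 and -0.0370 for lysosomal genes. They were 0.0268 and 0.0635 for proliferation, 0.0276 and 0.0137 for interferon-stimulated genes, 0.21 and 0.0258 for NRF2 targets, -0.0436 and -0.0286 for cholesterol synthesis, -0.0110 and -0.0503 for hypoxia and glycolysis, 0.0545 and -0.0193 for ribosome biogenesis and 0.0653 and 0.0191 for genes with upstream reading frames. Nuclear-retained RNAs were at -0.12 and 0.00276 and sex-linked genes at -0.12 and 0.17. In total RNA, the blocked fit without the pair that holds the library standing apart put nuclear-retained RNAs past camera in the lower direction. Their median there was -0.0776 (camera adjusted p = 0.0471, and 0.811 with an estimated correlation). The camera test had the opposite sign to the median for neural, myofibroblast and microtubule lists in total RNA and for nuclear-retained, cilium and upstream reading frame lists in ribosome-associated RNA.

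A larger share of macrophages in the HTT-deleted cultures may account for the rise of macrophage genes. The macrophage elastase Mmp12 fell in blocked ribosome-associated RNA (-1.10, SE 0.18), where all 18 listed markers lay above 0. A larger share of macrophages would not account for that fall if the Mmp12 reads came from macrophages, which was not tested. Over the 3 control ribosome libraries, the 203 genes that rose with the block, macrophage list left out, followed the macrophage score with a median slope of 0.821 (quartiles 0.559 and 0.974), against -0.0122 in 15319 other genes. The slope shows that these genes vary with the macrophage markers between control cultures. It cannot tell more macrophages from more of these transcripts per macrophage, since genes expressed in macrophages would follow the score under either. In blocked ribosome-associated RNA, removing a length trend left the markers' median at 0.829, which argues against length as the cause there. The test was not run in total RNA, which holds the library with the strongest length trend. HTT loss and the difference between the vectors cannot be told apart, since the score was higher in HTT-deleted libraries in 3 of 3 ribosome pairs and every control culture carried the H2B-eGFP vector.

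The H2B coding part of the control vector is a candidate source of the Hist1h2bf and Hist1h2bm reads. Over the 6 control libraries the ratio of the pair's counts stayed within counting error (1.47 to 3.25; chi-square 4.76, 5 degrees of freedom, p = 0.446) while their sum spanned 1.79 to 43.5 CPM. The other 14 tested histone genes had a median of 0.0354 (SD 0.348) in blocked ribosome-associated RNA, which argues against a fall of the class. A loss of these 2 genes alone cannot be told apart from the vector: 0 HTT-deleted libraries had a Hist1h2bf count within the control range, and the vectors differ between the same groups.

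Other splits were too few for a share under 0.05. Genes called were 0 in the real split and 0 at most in others for total and for ribosome-associated RNA (all 10 splits as many; edgeR, with 44 and 110 at an unadjusted p under 0.05; DESeq2 3 and 1, limma voom 0 and 0), and 3745 against 0 for the baseline comparison (1 of 10). Lists were 11 against 16 (7 of 10), 14 against 18 (6 of 10) and 12 against 24 (6 of 10). The number of lists past camera thus did not set the real split apart from other groupings of the same libraries. Over the 4 splits that part every pair, blocked fits called 0 against 0 genes in total RNA (4 of 4; 350 at an unadjusted p under 0.05) and 247 against 0 in ribosome-associated RNA (1 of 4), and 10 against 13 (3 of 4) and 15 against 18 lists (2 of 4). Other unpaired splits reached 1074 and 1843 genes at an unadjusted p under 0.05, a structure of the samples by culture.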
